A study of Homo sapiens with 4 samples.

How the data were processed

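ARPE-19 cells, an established human retinal pigment epithelial line, were sham washed or given adriamycin at 1 µM, 2 µM or 4 µM for 24 h, per the labels. Total RNA was extracted with Trizol and labelled with Cy3 as cRNA, per the labels' protocols. Each group is 1 array, so no spread between cultures can be estimated. Whether the arrays hold RNA of separate cultures, the time of the control and the step at which the spike-in RNA was added are not given in the sources used here. The title of the control sample carries a second number whose meaning is not given.

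The deposited scanner files hold intensity values of 1-colour scans, made with Agilent Feature Extraction 10.7.1.1 per the submitters' processing notes. Per the file headers, the 4 arrays were scanned from 1 slide and the processed intensity was background-subtracted and detrended within each array, with surrogate values for dim spots. It is not normalized between arrays. The array has 384 by 164 spots, with 58717 gene spots, 4259 control spots and 50599 gene probes, of which 902 probes are printed on 10 spots each, and probe positions are on hg19 per the file headers. The authors also deposited a value table, in log2 units with higher values for more signal, matched here for 50599 probes. Its 4 columns have identical distributions, each with a median of 4.50, so it had been quantile normalized between arrays. Each column correlated across probes with log2 of the processed intensity of its own array at 0.9989, 0.9997, 0.9998 and 0.9955. How the table was made is otherwise not given in the sources used here.

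The main value was log2 of the processed intensity from the scanner files. Spots that the scanner software marked as outliers were left out (357, 504, 505 and 394 on the control, 1 µM, 2 µM and 4 µM arrays), replicate spots were averaged, and each array's 75th percentile over gene probes was subtracted. Probes were named by transcript accession (28174), by current symbol (2618) or by an older symbol (620) through a RefSeq gene table, and 19187 kept the name the files give, which made 36400 gene names. A gene took the probe with the highest mean over the 4 arrays. Of 5885 genes with several detected probes, 574 had 1 probe at least 2-fold higher and another at least 2-fold lower at the same dose. A gene was counted in a comparison when the scanner software called its probe well above background on at least 1 of the arrays compared, and as higher or lower at a log2 difference of 1 or more. Where the probe was not well above background on 1 array, a fold is given as a bound, with the dim side set at the lowest value among probes well above background on that array, or at its own value where that was higher. Median replicate-spot SD was 0.052, 0.045, 0.046 and 0.061 log2, and the median scanner error 0.145, 0.145, 0.146 and 0.148, both of which are technical only.

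The comparisons were each dose with control and each dose with each lower dose, without a test. A dose trend was fitted with limma 3.58.1 in R 4.3.3 (dose in µM as a number, eBayes, Benjamini-Hochberg over 24593 genes), whose 2 residual degrees of freedom mix curvature with error. All 24 orderings of the doses over the arrays were refitted. Medians of 34 gene lists were compared with 10000 random lists of the same size, matched on mean expression in 20 bins. The lists covered p53 targets, the BCL2 family, death receptors and caspases, G2/M and mitosis, G1/S and DNA replication, replication-dependent histones, homologous recombination and Fanconi genes, DNA damage checkpoint, nucleotide and base excision repair, topoisomerases, drug transporters and doxorubicin metabolism. They also covered NF-kB and senescence-associated secretory genes, interferon response, immediate early genes, unfolded protein and integrated stress, heat shock, NRF2 and oxidative stress, cholesterol synthesis, cytosolic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, glycolysis and hypoxia, RPE identity, extracellular matrix, core transcription and elongation, and autophagy and lysosome, besides markers of 7 other cell types. Correlations and overlaps of the 3 comparisons with control were set beside values simulated for unchanged arrays against 1 shared control, with noise of 0.051 log2 (replicate spots) and 0.811 log2. The latter is the SD of the difference between the 1 µM and 2 µM arrays divided by the square root of 2. It holds any effect of dose between those arrays besides error.

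Gene lists, comparisons, thresholds and a rule for naming genes were chosen before the data were examined. The rule names the 12 highest and 12 lowest genes among those at least 2-fold higher or lower at all 3 doses, by their median difference (1022 and 855 eligible), the 5 highest and 5 lowest at each dose, the 10 highest and 10 lowest at 4 µM against 1 µM, up to 4 members of each list with the largest difference, the 5 with the lowest trend p in each direction, and a fixed set of genes that included CDKN1A, MDM2, GDF15, TOP2A, TOP1, TOP2B, MKI67, CCNB1 and ABCB1. It gave 193 measured genes, and 22 more were chosen after their values were seen, by the same ranks with spots in bright patches and single spots of spot rows 1 to 200 passed over. Of the genes the text names, ANGPTL7, APLN, DPYD, EFNB3, ERBIN and RPTOR come from that second choice alone. Names that are only clone, locus or accession identifiers were left out.

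Alternatives tried were scaling by the array median, by the 75th percentile over probes detected on all arrays, by quantile normalization, by the mean of 8 E1A spike-in probes and no scaling; normexp background correction with an offset of 50; no filter and a filter on both arrays; the mean over a gene's probes; outlier spots kept; a difference above 2 scanner errors; and the authors' values. Trend alternatives were log2 of dose plus 1, each array left out, and eBayes with trend and robust settings. Chosen after the data were examined were the dim side at its bound, leaving out bright patches of the control array (a spot over 3 log2 brighter than on every other array, with at least 4 such spots in the 5 by 5 block around it), leaving out genes measured on a single spot of spot rows 1 to 200, spike-in scaling for the trend and the dose profiles, and overlaps over genes well above background on at least 1 of the arrays in each of the 2 comparisons. Zinc finger genes were taken by their ZNF symbols.

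The calculations were tested on simulated data for 24593 genes with noise of 0.146 log2. The 2-fold count for 4 µM against control called 0 of 24393 unchanged genes, 1 of 67 changed by a log2 of 0.5, 67 of 67 at 1.5 and 66 of 66 at 3. The limma trend called 12 unchanged genes, 13 of 67 at 0.5, 67 of 67 at 1.5 and 66 of 66 at 3. The simulated noise was of the size of the median scanner error and alike for all genes, and the changes were linear in dose. Differences between cultures, stray bright spots and curved responses were not simulated. The simulation therefore checks the calculations alone and gives no rate of false calls for the real arrays. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.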

Results

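Gene expression was measured in ARPE-19, an established line of human retinal pigment epithelium, after 24 h with adriamycin (doxorubicin), an anthracycline that intercalates into DNA and poisons topoisomerase II. The groups were 1 µM, 2 µM and 4 µM adriamycin and a sham-washed control, for which the labels give no time. Each group was a single Agilent 1-colour array, 4 arrays in all (n = 1 array per group), so no difference has a replicate check and no p-value is given across genes for a comparison of arrays. The labels do not say whether the RNA of the 4 arrays came from separate cultures. Of 50599 gene probes, 28616 (56.6%) were well above background on the control array, 27915 (55.2%) at 1 µM, 28089 (55.5%) at 2 µM and 24278 (48.0%) at 4 µM. A gene took the value of its brightest probe, which gave 24593 genes well above background on at least 1 array and 17286 on all 4. No spot was saturated. The ± beside a log2 value is the scanner's own error for the pair of arrays, and the number of arrays limits the precision more than that error does.

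The arrays differed in brightness with dose. Compared with control, the 75th percentile of the gene probes, to which each array was scaled, was lower by a log2 of -0.06 at 1 µM, -0.89 at 2 µM and -1.87 at 4 µM. The mean of 8 spike-in probes, synthetic sequences for an RNA added in known amounts, differed from control by only 0.01, -0.11 and -0.05. The choice of scale therefore moves every gene: the median log2 difference over all genes was 0.00, 0.25 and 0.66 at 1, 2 and 4 µM with the 75th percentile and -0.07, -0.53 and -1.16 with the spike-in. Log2 values are given on the 75th-percentile scale, and a direction that flips on the spike-in scale is stated with it. A gene list printed with a percentile is set beside random lists matched on expression, from which the scale cancels. List medians printed without a percentile have no such comparison beside them. Among genes often taken as references, chosen after their values were seen, ACTB (beta-actin) had a log2 of 1.55 at 4 µM on the first scale and -0.26 on the second (-0.10 with quantile normalization), while TBP, the TATA-binding protein of the basal transcription machinery, had -2.03 and -3.84. TBP was the exception, as all the other reference genes looked at had 0.98 to 2.26 on the first scale and -0.83 to 0.44 on the second.

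**Figure D1:**
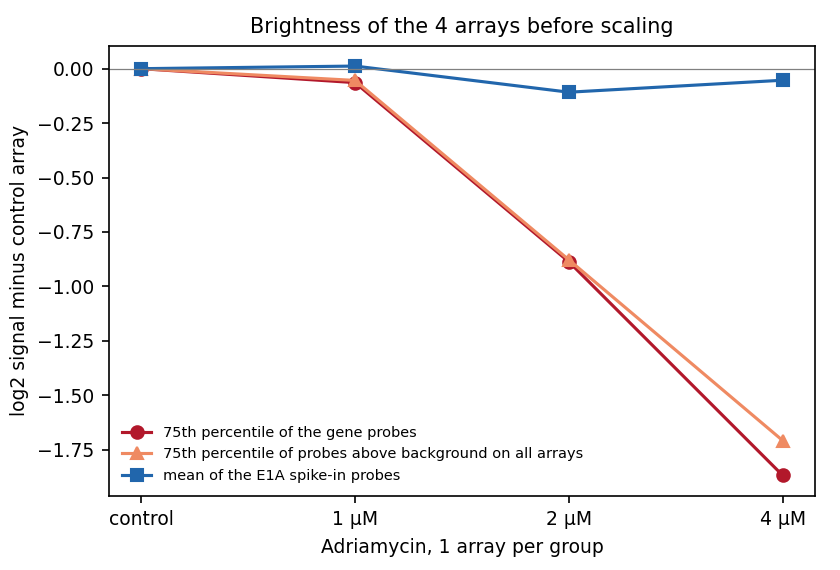
Log2 difference from the control array (y axis) at each adriamycin dose in µM (x axis) of the 75th percentile of the gene probes, the 75th percentile of the probes well above background on all arrays and the mean of 8 spike-in probes, 1 array per point. At 4 µM the 75th percentile lay at -1.87 and the spike-in mean at -0.05.

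At 1 µM the question was which transcripts differ from control at the lowest dose. GDF15, a secreted stress cytokine, was 262-fold higher (log2 8.03 ± 0.21; probe on chromosome 19, 18499890 to 18499949, hg19). AKR1B10, an aldo-keto reductase that reduces carbonyl groups of drugs and lipids, was 260-fold higher (8.02 ± 0.21; chromosome 7, 134225939 to 134225998), and its close paralogue AKR1B15, whose transcript a probe may not separate from it, was 277-fold higher. The imprinted long non-coding RNA H19 (chromosome 11, 2016674 to 2016733) was at least 265-fold higher and the metalloprotease gene ADAMTS8 at least 55.7-fold higher. "At least" marks a probe not well above background on 1 of the compared arrays, for which a bound is given in place of a fold. AREG, the EGFR ligand amphiregulin, was 65.7-fold higher. Downward, COL1A1, a chain of type I collagen, was 14.3-fold lower, DPYD, which degrades pyrimidines, 12.9-fold lower, and EFNB3, an ephrin ligand, 24.8-fold lower. For DPYD a second detected probe had a log2 of -1.49 beside -3.69.

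The list of p53 target genes stood out at 1 µM. Of 52 measured, 38 were at least 2-fold higher and 1 lower, with a median log2 of 1.76, at percentile 100 of 10000 matched random lists (random median 0.01; 1.69 on the spike-in scale). TP53I3, a quinone oxidoreductase linked to oxidative stress, was 36.2-fold higher, SFN, the cell cycle brake 14-3-3 sigma, 22.1-fold, and PMAIP1, the BH3-only death protein NOXA, 11-fold. CDKN1A, which encodes the CDK inhibitor p21 (chromosome 6, 36652178 to 36652237), was 2.26-fold higher (1.17 ± 0.20). MDM2, a ubiquitin ligase (chromosome 12, 69238891 to 69238950), was only 1.36-fold higher. In the BCL2 family, which sets the threshold for mitochondrial death, the median was 0.33 (0.13 without single-spot genes in spot rows 1 to 200 of the array), with 5 of 19 members at least 2-fold higher, among them BIK 5.89-fold and BAK1 2.49-fold, and 2 lower.

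Genes of G2/M and mitosis went the other way: 32 of 60 were at least 2-fold lower and 0 higher (median -1.07, percentile 0). CCNB1, the cyclin that drives entry into mitosis, was 4.09-fold lower, CENPA, the centromeric histone, 4.03-fold, and the kinesin KIF11, which separates spindle poles, 3.02-fold. The proliferation marker MKI67 was 1.46-fold lower. Topoisomerases as a list had a median of -0.10, with TOP2A 1.45-fold and TOP2B 2.89-fold lower and TOP1 1.25-fold higher. Medians were also under those of nearly all random lists for homologous recombination and Fanconi genes (-0.67, percentile 0), DNA damage checkpoint genes (-0.70, percentile 0), ribosome biogenesis (-0.64, percentile 0), glycolysis and hypoxia (-0.71, percentile 0), cholesterol synthesis (-0.56, percentile 0.06) and G1/S and DNA replication (-0.32, percentile 0.2). Single members were WRN, a helicase of DNA repair, 4.84-fold lower, UTP20, a ribosome assembly factor, 3.56-fold, PDK1, which inhibits pyruvate dehydrogenase, 6.97-fold, SQLE, a sterol epoxidase, 3.02-fold, and POLA1, the catalytic subunit of the priming polymerase, 6.66-fold lower.

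The NF-kB and senescence-associated secretory list had a median of 0.86 at 1 µM and the interferon list 0.91, each at percentile 100, with 19 of 40 and 15 of 36 members at least 2-fold higher and 4 and 3 lower. CSF3, a granulocyte growth factor, was at least 18.2-fold and ISG15, a ubiquitin-like interferon product, 18.5-fold higher, while IFI44, another interferon-induced gene, was 10.9-fold lower. Autophagy and lysosome genes had a median of 0.58 (percentile 100), which became -0.24 without single-spot genes in spot rows 1 to 200 of the array. NRF2 and oxidative stress genes had a median of 0.36 (percentile 99.54) and RPE identity genes 0.35 (percentile 98.22). Nucleotide and base excision repair had -0.26 (percentile 4.41). Heat shock had -0.23 (percentile 4.2), but -0.05 without single-spot genes in those spot rows, and of its members 6 were at least 2-fold higher and 1 lower.

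In all, 4191 genes were at least 2-fold higher and 2834 at least 2-fold lower at 1 µM, of 23054. Scaling by array medians turned this split to 3282 higher and 4489 lower, and the spike-in scale gave 3946 and 3178.

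**Figure D2:**
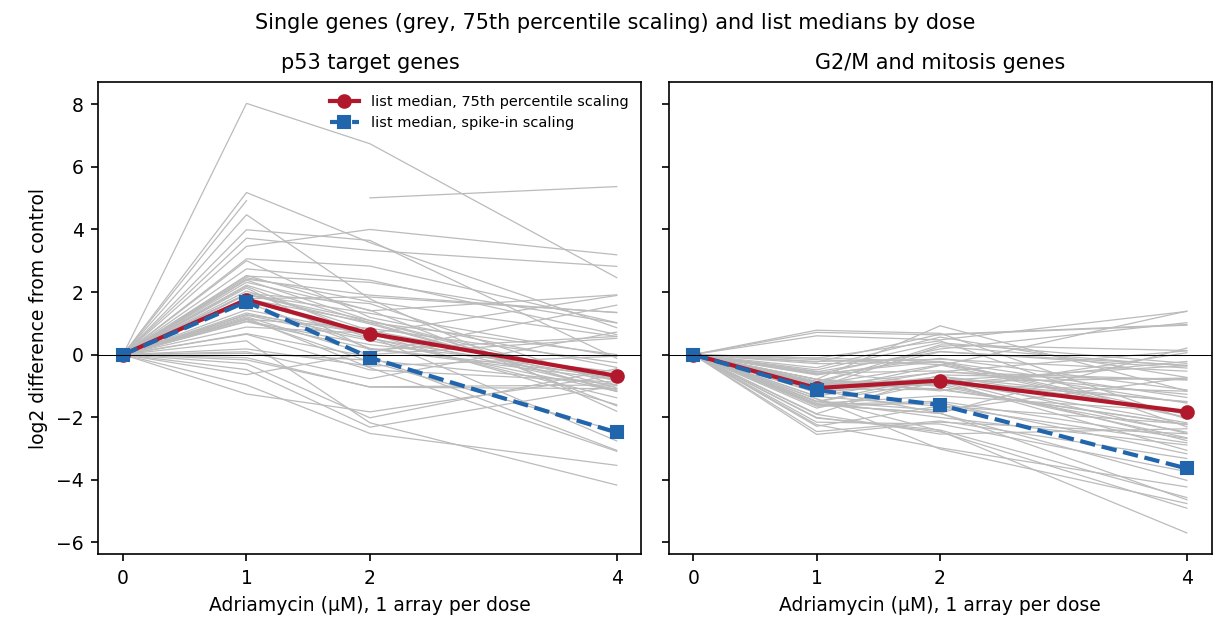
Log2 difference from control (y axis) at each adriamycin dose in µM (x axis), 1 array per dose, for single p53 targets and mitotic genes (grey lines, 75th-percentile scale) and their list medians on the 75th-percentile scale (red) and the spike-in scale (blue). The p53 target median was 1.76 at 1 µM and -0.68 at 4 µM (1.69 and -2.49 with the spike-in), and the mitotic median -1.07 and -1.83 (-1.14 and -3.64).

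APLN, the secreted peptide apelin, was 324-fold higher at 2 µM than in control (8.34 ± 0.10), ADAMTS8 at least 202-fold, RPRML, a relative of the cell cycle inhibitor reprimo, at least 114-fold, and SAA4, the constitutive serum amyloid A, at least 81.0-fold. AKR1B10 was 75.7-fold higher and GDF15 had a log2 of 6.74. Of the lower genes, NREP, a neuronal regeneration protein, was 66.2-fold, ANGPTL7, an angiopoietin-like protein, at least 50.4-fold, DPYD 45.3-fold and COL1A1 at least 35.5-fold lower. Second detected probes had smaller log2 values for DPYD (-1.64 beside -5.50) and RPRML (2.79 beside 8.79).

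The p53 target list was less high at 2 µM, with a median of 0.67 (percentile 99.9; -0.10 on the spike-in scale) and 22 of 52 members at least 2-fold higher against 7 lower. PMAIP1 was 16-fold and TP53I3 12-fold higher, whereas 4 MDM2 probes had log2 values of -1.31, -0.71, -2.18 and -0.44 and CDKN1A had -0.42. Mitotic genes had a median of -0.83 (percentile 0), with BUB1B, a spindle checkpoint kinase, 8.10-fold lower. Homologous recombination and Fanconi genes had a median of -0.57 (percentile 0.55), ribosome biogenesis -0.74 (percentile 0), nucleotide and base excision repair -0.42 (percentile 1.19) and core transcription and elongation -0.39 (percentile 1.16). NBN, part of the complex that senses DNA breaks, was 9.23-fold lower, RAD50, its partner, 4.79-fold, and PARP2, a break-activated polymerase, 5.98-fold. The secretory list had a median of 1.05 and the interferon list 0.93, each at percentile 99.99, and the unfolded protein list had 0.74 (percentile 99.88; -0.03 on the spike-in scale). FOSB, an AP-1 subunit transcribed within minutes of a stimulus, was 24.3-fold higher. Replication-dependent histones had a median of 0.79, at percentile 99.98, but their near-identical copies share probes and these values are uncertain. At this dose 6012 genes were at least 2-fold higher and 4169 lower, of 23394. The split was 4028 and 6695 with median scaling, 3420 and 8132 with the spike-in, and 3224 and 8906 with no scaling.

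Compared with control, FOSB was 79.9-fold higher at 4 µM (6.32 ± 0.21), and EGR2, a zinc finger early-response factor, 110-fold higher. NR4A3, an early-response orphan receptor, was at least 89.7-fold higher on a single spot of spot rows 1 to 200, and its other probe was not well above background on any array. GJB2, the gap junction protein connexin 26 (chromosome 13, 20761915 to 20761974, 10 spots), was at least 142-fold and the zinc finger gene INSM2 at least 105-fold higher. RGS16, which shortens G protein signals, was 552-fold higher, with its spot in a bright patch of the 4 µM array, and a second probe in the later spot rows had a log2 of 8.60 beside 9.11. GADD45G, a growth arrest gene of the DNA damage response, was 45.0-fold higher. Among the lower genes, SRSF3, a splicing factor (chromosome 6, 36570424 to 36570483), was 85.4-fold lower (-6.42 ± 0.21), ERBIN, an adaptor of receptor signalling, 64.1-fold, and RPTOR, the mTORC1 scaffold, 51.8-fold lower.

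p53 targets were below control at 4 µM, with 11 of 52 at least 2-fold higher and 16 lower (median -0.68, percentile 0, random median 0.63; -2.49 on the spike-in scale, and -0.43 without single-spot genes in spot rows 1 to 200). CDKN1A was 8.54-fold lower (-3.09 ± 0.24), SFN 3.51-fold, BAK1 7.95-fold and MDM2 18.0-fold lower, where 4 MDM2 probes had log2 values of -2.80, -2.76, -4.17 and -0.62. Against these, PMAIP1 was 9.13-fold and GDF15 5.50-fold higher, and TP53I3 had a log2 of 0.86 (-0.95 on the spike-in scale). AKR1B10 had a log2 of 1.27, which became -0.54 on the spike-in scale, and ISG15 had 1.59, which became -0.22. The mitotic list had its lowest median of the 3 doses, with 39 of 60 members at least 2-fold lower than control (median -1.83, percentile 0). From 1 µM to 4 µM its median was -0.57 (percentile 0.09), with 25 members at least 2-fold lower and 8 higher. Compared with control, SPC25, a kinetochore component, was 51.9-fold, BUB1B 27.1-fold, KIF11 24.9-fold and CCNB1 23.7-fold lower. The proliferation marker MKI67 had a log2 of only -0.43 at 4 µM (0.10 at 2 µM), and -1.46 and -0.14 at its other probes at 4 µM. TOP2A was 2.26-fold and TOP2B 2.36-fold lower, and the topoisomerase list had a median of -1.13 (percentile 3.93).

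Core transcription and elongation genes had a median of -0.91 at 4 µM (percentile 0.02), with AFF4, a scaffold of the super elongation complex, 8.74-fold and CDK7, the kinase of TFIIH, 7.74-fold lower. The immediate early list as a whole was low (-0.75, percentile 0.1), with 11 members at least 2-fold higher and 12 lower. Homologous recombination and Fanconi genes had a median of -1.15 (percentile 0.02), checkpoint genes -0.48 (percentile 4.14; -0.10 without single-spot genes in spot rows 1 to 200) and death receptor and caspase genes -0.28 (percentile 2.84), among them TNFRSF1A, the main TNF receptor, 17.1-fold lower. Ribosome biogenesis had a median of -0.61 (percentile 0.32), which was 0.06 without single-spot genes in spot rows 1 to 200.

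Of the cytosolic ribosomal protein genes, all 78 were at least 2-fold higher at 4 µM on the 75th-percentile scale (median 1.76, percentile 95.98), and 0 were on the spike-in scale (median -0.05). Nuclear genes of oxidative phosphorylation had 1.60 (-0.21 with the spike-in), NRF2 and oxidative stress genes 1.57 (-0.25), autophagy and lysosome genes 1.42 (-0.40), the secretory list 1.35 (-0.46) and extracellular matrix genes 1.13 (-0.68), so each of these directions depends on the scale. Beside random lists, the secretory list (percentile 99.88) and NRF2 (98.89) were high, and the interferon list (0.59, percentile 58.31, and -1.22 with the spike-in) was not. Autophagy (99.43) was high but had a median of -0.70 over the 12 of its 28 genes left without single-spot genes in spot rows 1 to 200. GPX2, a glutathione peroxidase, was 20.6-fold higher, and MMP3, a matrix metalloprotease, at least 24.7-fold. Drug transporter genes had medians of 0.21, 0.33 and 0.42 at the 3 doses (-0.45 and -1.40 at 2 and 4 µM with the spike-in, and -0.07 at 2 µM without single-spot genes in spot rows 1 to 200) and doxorubicin metabolism genes 0.25, 0.36 and 0.27 (-0.42 and -1.55), between percentiles 15.09 and 87.9 of random lists. ABCC2, an efflux pump for conjugated drugs, was at least 8.88-fold higher at 4 µM and AKR1C3, a reductase that acts on doxorubicin, 2.57-fold lower, while the efflux pump ABCB1 was not well above background on any array.

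At 4 µM 9241 genes were at least 2-fold higher and 4559 lower, of 22432. With quantile normalization the split was 5847 and 5838, with median scaling 3549 and 7761, with the spike-in 1462 and 12112, and with no scaling 1424 and 12393.

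**Figure D3:**
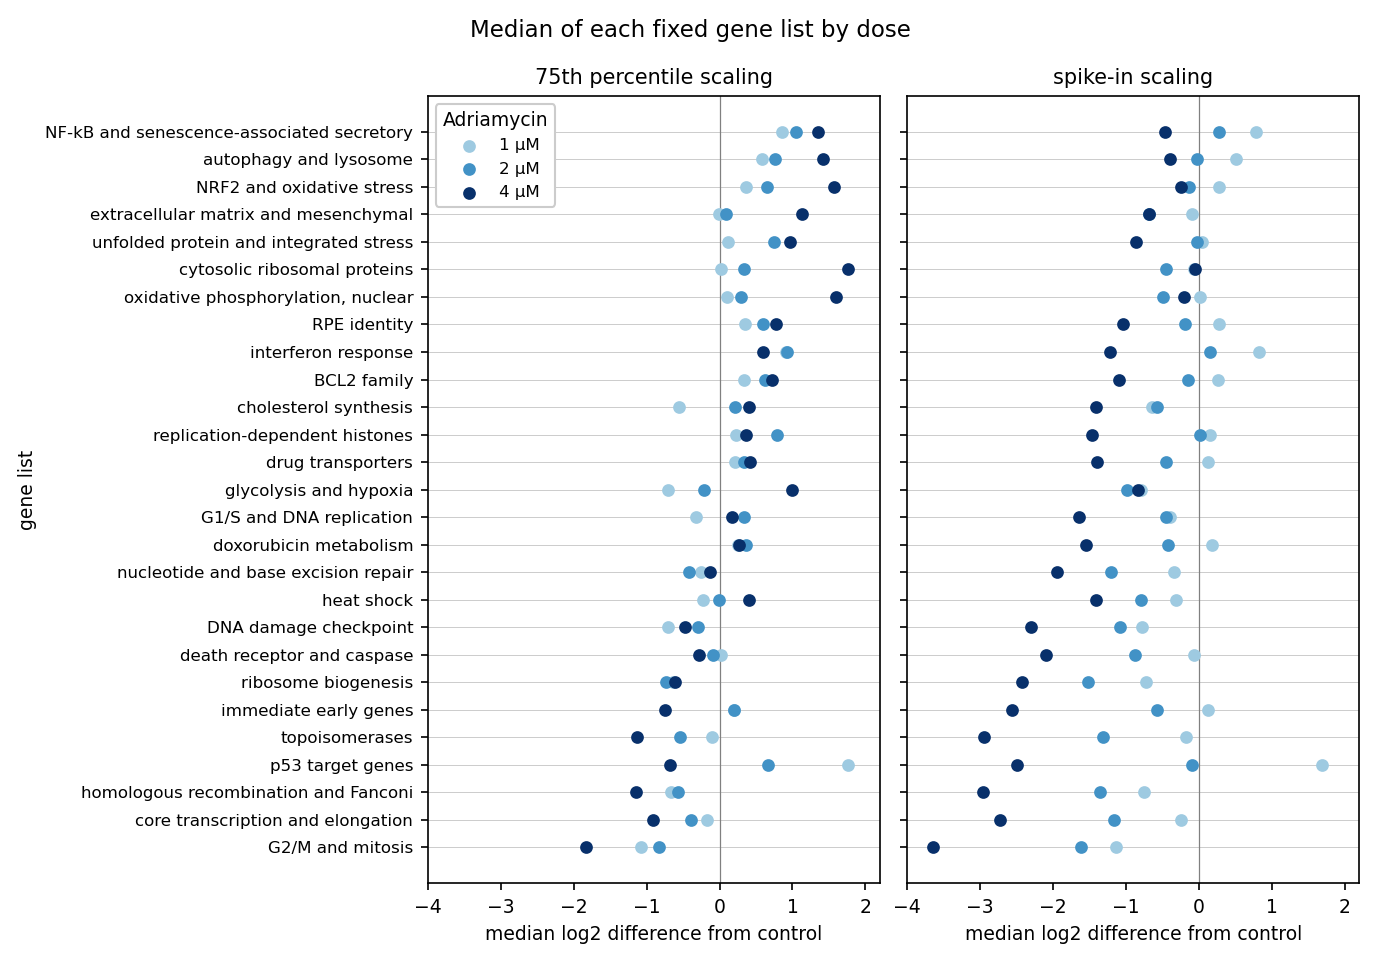
Median log2 difference from control (x axis) of fixed gene lists (y axis) at 1, 2 and 4 µM adriamycin, on the 75th-percentile scale and on the spike-in scale. The ribosomal protein median at 4 µM was 1.76 on the first scale and -0.05 on the second, while the mitotic median was below 0 at each dose on both.

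Between the doses the question was whether the response kept its direction as the dose went up. From 1 µM to 4 µM the p53 target list was lower by a median log2 of -2.04 (percentile 0), with 37 of 53 members at least 2-fold lower and 3 higher. ANKRD1, a nuclear cofactor of stretch and YAP signalling, was 4.72-fold higher than control at 1 µM and at least 245-fold lower at 4 µM than at 1 µM. In the same comparison SFN was 77.6-fold, CYSRT1, a cysteine-rich epidermal protein, 73.4-fold, and GDF15 47.6-fold lower. In the other direction, FOSB was 50.2-fold, GPX2 31.9-fold, EFNB3 28.9-fold and DPYD 14.9-fold higher at 4 µM than at 1 µM. Glycolysis and hypoxia genes had a median of 1.70 (percentile 99.84; -0.04 with the spike-in), with PDK1 12.5-fold higher. Ribosomal protein genes had 1.74 (0.00 with the spike-in). Death receptor and caspase genes (-1.07, percentile 0.06), core transcription and elongation (-0.86, percentile 0.04) and immediate early genes (-0.84, percentile 0.07) were lower at 4 µM than at 1 µM.

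Of the genes at least 2-fold higher at 1 µM, 2031 of 4191 were back by 2-fold or more at 4 µM and 270 lay at least 2-fold below control there. On the spike-in scale these counts were 3341 of 3946 and 1135. Of the genes lower at 1 µM, 1559 of 2834 were back by 2-fold or more at 4 µM, against 314 of 3178 with the spike-in. These genes were picked by the same 1 µM value from which the return was measured, so noise or stray signal on that array also returns. Of all genes counted at 4 µM against 1 µM, 23.8% were at least 2-fold lower and 37.3% higher (56.5% and 5.3% with the spike-in). The counts do not separate a turn in the response from that selection. Genes at least 2-fold higher at all 3 doses numbered 1471 (486 with the spike-in), and 1128 were lower at all 3 (2458). At 2 µM against 1 µM, 3380 genes were higher and 2536 lower, of 22766, and the split was 2533 and 3631 with median scaling, 1603 and 6913 with the spike-in and 1460 and 8002 with no scaling. At 4 µM against 2 µM the split was 6271 and 4804, of 22214. It became 4067 and 6280 with median scaling, 4505 and 5637 with quantile normalization, 1447 and 9771 with the spike-in and 1562 and 9473 with no scaling. At 4 µM against 1 µM it was 8290 and 5297, of 22245, and 6094 and 6255 with quantile normalization, 5134 and 7353 with median scaling, 1187 and 12560 with the spike-in and 1128 and 12888 with no scaling.

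A dose trend across the 4 arrays was the only test run. The genes with the lowest trend p included ZMIZ1, a coactivator of nuclear receptors, which had log2 differences of -1.44, -3.03 and -5.42 at the 3 doses but -0.81, -0.50 and 0.05 at a second detected probe, and ACTA1, a muscle actin, which was at least 5.33-fold higher at 2 µM and at least 48.2-fold at 4 µM. By limma 0 of 24593 genes passed at an adjusted p under 0.05, while 5842 had an unadjusted p under 0.05. Without the 1 µM array the unadjusted count was 2453. Adjusted over the list alone, 8 immediate early genes and 6 mitotic genes passed, beside 2 of the NRF2 list and 1 each of the drug transporter, glycolysis and extracellular matrix lists, and over all genes 0 did. With 2 residual degrees of freedom the fit takes curvature for error, so a turn in the response counts against a gene.

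Some genes had the same direction in the 3 comparisons with control. GDF15 and APLN were higher and SRSF3 and CCNB1 lower at every dose on both scales. Over the genes counted in both comparisons, a filter chosen after the results were seen, 2782 of 22300 were at least 2-fold higher at both 1 and 2 µM (765.5 if independent) and 2090 lower (529.8). At 1 and 4 µM these were 1686 (1134.6) and 1212 (595.3) of 21703, and at 2 and 4 µM 3219 (1822.4) and 2354 (866.5) of 21934. Because the comparisons share the control, unchanged arrays overlap too. With a simulated noise of SD 0.811 they shared 1878 higher and 1784 lower genes at 1 and 2 µM, 1817 and 1842 at 1 and 4 µM, and 1846 and 1834 at 2 and 4 µM, and with the noise of replicate spots 0. The SD of 0.811 was taken from the 1 and 2 µM arrays, so it holds any effect of dose between them. An overlap below the simulated one therefore does not show that shared effects are absent. Against the wider noise, the shared genes at 1 and 4 µM were fewer than simulated in both directions, as they were over the 17286 genes well above background on all arrays (1288 higher against 1415, 667 lower against 1452). Over all 24593 genes, which include some detected only on an array outside the comparison, they were more than simulated for higher genes (3204 against 2051) and fewer for lower genes (1212 against 1939). Over the same 24593 genes the shared higher genes were fewer than simulated with quantile normalization (1665 against 1990) and with normexp (1385 against 2014). The simulated noise was the same for every setting and centred at 0. The difference between the 1 and 2 µM arrays had an SD of 1.17 in the main values and 1.16 with quantile normalization. It was 0.69 with normexp and 0.84 over genes well above background on both arrays. The noise was thus too wide for normexp and probably for genes detected on all arrays, so those comparisons decide nothing. The direction for higher genes differed between the main values and quantile normalization, and the simulation does not settle it. At 1 and 2 µM all genes gave 3535 higher (2025 simulated) and 2094 lower (2047), and at 2 and 4 µM 4911 (2009) and 2354 (1984). Across all 24593 genes, which are not independent replicates, Pearson's r was 0.744 for 1 and 2 µM (Spearman's rho 0.761), 0.458 for 1 and 4 µM (0.441) and 0.680 for 2 and 4 µM (0.674). Unchanged arrays simulated against 1 shared control gave r of 0.499, 0.506 and 0.502, so that of 1 and 4 µM was under the simulated value. The covariances were 1.80, 1.20 and 2.12, against 0.0026 simulated with the noise of replicate spots and 0.665, 0.653 and 0.660 with the wider noise. Part of the excess may come from the shared control array, which cannot be split, and on arrays with none in common r was -0.295 between 1 µM against control and 4 µM against 2 µM, 0.109 between 2 µM against control and 4 µM against 1 µM, and 0.437 between 4 µM against control and 2 µM against 1 µM. Each of these sets an effect against control beside a step between doses, so none is a correlation of the effects of 2 doses.

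Some extreme values lay on spots in bright patches or in spot rows with stray bright spots. ADAM29, LOXHD1, SYT12, EMX2, GK3, CNGA2 and PLPBP, which the naming rule picked and which were lower at every dose, had their spot in a patch of the control array where neighbouring spots were over 3 log2 brighter than on every other array. Among 13 genes in such patches with other detected probes, the patch probes had a median log2 of -9.83 and 28 other detected probes of the same genes -0.33. Patch spots were picked for being brighter on the control array, so the low value of the patch probes follows in part from that choice. Of the genes just named, ADAM29 (-2.59) and LOXHD1 (-1.74) were still lower at their other detected probe, by the median over the 3 doses, and SYT12 had 8.28. EMX2, GK3, CNGA2 and PLPBP had no other probe to compare. By the same rule the 4 µM array had more spots in bright patches, 153 against 37 on the control array. The 1 and 2 µM arrays had 9 and 10. Those of the 4 µM array lay in spot rows 2 to 115, and 114 of their 124 gene spots carried no outlier mark. The patch alternative and the comparison with other probes covered the control's patches alone, so high values at 4 µM on such spots are unsure. PRODH (proline dehydrogenase), 442-fold higher at 1 µM on a spot of spot rows 1 to 200, had log2 values there of 6.52 at a probe in the later spot rows and 0.66 at another. NTN1 (netrin 1, at least 246-fold at 1 µM), SCN4B (a sodium channel subunit, at least 243-fold) and NPTX2 (a neuronal pentraxin, at least 245-fold at 2 µM) were dim in control and had their detected probes on single spots in spot rows 1 to 200, as had CSF3, MMP3, NR4A3 and ABCC2. On the treated arrays, replicate spots of dim probes in those spot rows were often far brighter than their own probe: 6.24% lay over 2 log2 above it at 1 µM, against 0.131% in the spot rows after 200. The percentages were 5.46 and 0.342 at 2 µM, 4.97 and 0.338 at 4 µM, and 1.09 and 2.42 on the control array. A gene with 1 spot there has no such check. Among replicate spots of bright probes (median log2 over 7) 0% lay so far above on the treated arrays, in either set of spot rows. A list of detected genes can thus also move because fewer members are left. All 28 autophagy genes and all 43 ribosome biogenesis genes were well above background on every array, and 12 and 17 were left. Without single-spot genes in spot rows 1 to 200, 1719 genes were higher and 1514 lower at 1 µM of 11244, 2531 and 2174 at 2 µM of 11343, and 4257 and 2321 at 4 µM of 10933. Other list medians that this moved by over 1.5 times in the same direction included, at 1 µM, G1/S and DNA replication (-0.49), topoisomerases (-0.50), NRF2 (0.57), RPE identity (0.72), drug transporters (0.42) and doxorubicin metabolism (0.56), at 2 µM replication-dependent histones (1.42), at 4 µM the secretory list (0.89) and doxorubicin metabolism (0.59), and from 1 µM to 4 µM immediate early genes (-1.33).

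**Figure D4:**
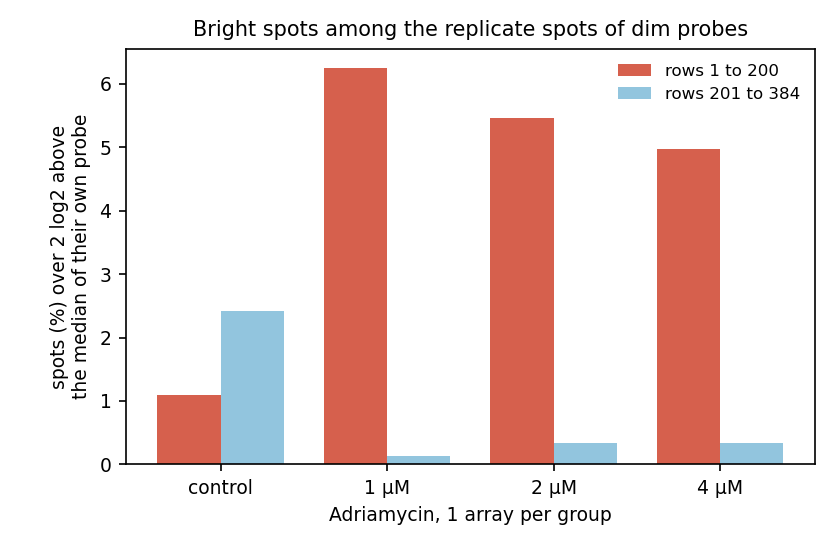
Percent of replicate spots of dim probes over 2 log2 brighter than the median of their own probe (y axis) on each array (x axis), in spot rows 1 to 200 and in the spot rows after 200. At 1 µM the upper spot rows had 6.24% and the others 0.131%, and on the control array the order was the other way, 1.09% and 2.42%.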

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

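For the p53 target genes the test on zinc finger genes was chosen before its result was seen, and the tests of scaling and of defective spots, like those of array brightness, the control-array patches and stray signal, only after it.

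p53 target genes lay above control at 1 µM (median log2 1.76, 1.69 with the spike-in) and below it at 4 µM (-0.68 and -2.49), a difference in direction between the dose groups that was not tested, with a median of -2.04 from 1 µM to 4 µM. The choice of scaling is argued against as the whole cause, since the list's median at 4 µM minus that of its matched random lists, from which any scale cancels, was -1.31. For the difference from 1 µM to 4 µM defective spots are argued against too, since without single spots of spot rows 1 to 200 its median was -1.74. The part below control is less sure, as the median at 4 µM was -0.43 without those spots. What stays open is a loss of short-lived transcripts at 4 µM, which may account for part of it: zinc finger genes, known for short-lived transcripts, had a median of -0.89 from 1 µM to 4 µM (random median 0.37) at percentile 0.0 of random lists, with 195 of 422 at least 2-fold lower and 40 higher, and at 1 µM against control -0.07 (percentile 6.53). The dose itself is a biological explanation that stays open as untested, and with 1 array per dose so does an unknown difference between the arrays.

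The same difference in direction, each not tested, set apart CDKN1A (log2 1.17 at 1 µM and -3.09 at 4 µM, a difference of -4.27), BAK1, a pore-forming death effector (1.31 and -2.99, -4.30), SFN (4.47 and -1.81, -6.28) and CYSRT1 (3.11 and -3.08, -6.20).

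The 75th percentile of the gene probes differed from the control array by a log2 of -1.87 at 4 µM. A lower brightness of the whole array is argued against, since the spike-in mean differed from control by -0.053. Less labelled RNA of every gene alike is argued against as well, since the cytosolic ribosomal protein genes had a median of -0.05 at 4 µM with spike-in scaling. A smaller share of labelled RNA from many genes, with abundant housekeeping transcripts kept, may remain, and the 200 brightest probes held 36.0% of the signal at 4 µM and 28.3% on the control array. The step at which the spike-in was added is not given, so its level does not show the amount of RNA per cell, and the effect of dose on that amount was not tested.

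Genes over 100-fold lower on every treated array, and genes dim in control and much higher on treated arrays, may in part be array defects. For the first, a smear of signal over neighbouring spots of the control array is a candidate explanation: for 13 genes with other detected probes, the median log2 difference at those probes was -0.33, against -9.83 in the patches. The patch value follows in part from how patch spots were picked, by their higher signal on the control array. The other detected probes of ADAM29 (-2.59) and LOXHD1 (-1.74) were still lower, and EMX2, GK3, CNGA2 and PLPBP had no other probe. For the second, stray signal on dim spots is a candidate explanation, since 6.24% of replicate spots of dim probes in spot rows 1 to 200 lay over 2 log2 above their own probe at 1 µM and 0.131% in the spot rows after 200. Of the 53 such spots at 1 µM in the upper spot rows 50 carried an outlier mark and were left out. A single spot can carry an outlier mark too, but has no replicate spots to be set beside. In the bright patches of the control array 30 of 37 gene spots carried no mark, and in those of the 4 µM array 114 of 124. These tests do not exclude an effect of adriamycin on single genes among them, which was not tested.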

How the results depend on the processing

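The alternatives without single spots of spot rows 1 to 200, spike-in scaling of the dose profiles and of the trend, and correlations over genes detected in each comparison, were chosen only after the results were seen. Of 16 alternatives per count of genes at least 2-fold higher or lower, 12 stayed within 1.5 times the count at 1 µM, 14 at 2 µM and 13 at 4 µM against control. At 1 µM (7025) the others were 3722 with normexp, 3198 with normexp and quantile normalization and 4476 with detection required on both arrays, at 2 µM (10181) 5619 with normexp and quantile normalization, and at 4 µM (13800) 7290 with that setting and 25805 with no filter. At 2 µM against 1 µM (5916) no scaling gave 9462, normexp 3005, normexp with quantile normalization 2444 and detection on both arrays 3747. At 4 µM against 2 µM (11075) normexp gave 5865, normexp with quantile normalization 5611 and no filter 20898, and at 4 µM against 1 µM (13587) the last pair gave 7503 and 24457. Normexp with an offset shrinks differences of dim probes and the filters change how many genes are counted, by construction. Without single spots of spot rows 1 to 200, which leaves fewer genes, the 6 counts were 3233, 4705, 6578, 2411, 4970 and 6319. Spike-in scaling gave 486 genes higher at all doses (1471), 2458 lower (1128), 3341 that were higher at 1 µM and back at 4 µM (2031) and 314 lower and back (1559). The number of list medians at 2-fold, 17 in all, was 9 with quantile normalization and with the authors' values, 34 with no scaling and 31 with the spike-in, and of the 17 themselves 6, 6, 5 and 5 stayed at 2-fold in the same direction. Medians at 4 µM that reversed with no scaling and with the spike-in were the secretory list (-0.51 and -0.46), NRF2 (-0.30 and -0.25), ribosomal proteins (-0.11 and -0.05), oxidative phosphorylation (-0.26 and -0.21), extracellular matrix (-0.74 and -0.68), autophagy (-0.45 and -0.40), and haematopoietic (-0.67 and -0.62), endothelial (-0.87 and -0.82) and neuronal markers (-0.85 and -0.80). Without single spots of spot rows 1 to 200 autophagy had -0.70 and neuronal markers -0.70, and the cause was not tested. Of 208 differences at 2-fold of genes named in the text, no scaling reversed 5 and took 5 under 2-fold, the spike-in reversed 4 and took 5 under 2-fold, and the reversed ones at 4 µM were ACTB (-0.32 and -0.26), AKR1B15 (-0.86 and -0.81), AKR1B10 (-0.60 and -0.54), ISG15 (-0.28 and -0.22) and, with no scaling alone, ROM1 (-0.04). The other 8 alternatives kept 184 to 208 and reversed ACTB alone, with quantile normalization (-0.10), normexp with quantile normalization (-0.12) and the authors' values (-0.09). The correlation of 1 and 2 µM was 0.799 over genes detected on all arrays and 0.827 over genes detected in each comparison. That of 1 and 4 µM was 0.377 with quantile normalization and 0.380 over genes detected on all arrays, and that of 2 and 4 µM 0.622 with quantile normalization. On arrays with none in common, where no control is shared, r was -0.295 for 1 µM against control and 4 µM against 2 µM. It was 0.109 for 2 µM against control and 4 µM against 1 µM, and 0.437 for 4 µM against control and 2 µM against 1 µM. These last values set an effect against control beside a step between doses, so they are not the same correlations under another setting. The limma trend called 0 genes under each of 16 alternatives, with 2453 to 14749 at an unadjusted p under 0.05 (5842 in the trend reported), and the array whose removal moved that count by over 1.5 times was the 1 µM array (2453). As the real order of the doses gave 0 adjusted calls, 24 of 24 orderings gave as many by construction (the highest other 18), so their count decides nothing about chance. The real order had the most genes at an unadjusted p (5842, next 4588). Signal over background limits the dim genes, for which bounds alone are given. No paired analysis was possible because the groups share fewer than 2 replicate numbers.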

Other observations

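The medians without single spots of spot rows 1 to 200 were chosen only after the results were seen, and no explanation is offered here.

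Marker genes of other cell types were looked at as a background for the RPE list, although ARPE-19 is a cultured line. RPE identity genes, which include the retinol carrier TTR (at least 5.09-fold higher at 1 µM) and TYR, the first enzyme of melanin synthesis (at least 3.47-fold), had medians of 0.35, 0.59 and 0.78 at the 3 doses, and -0.19 and -1.04 at 2 and 4 µM with spike-in scaling. Haematopoietic markers had medians of 0.23, 0.46 and 1.19 (-0.32 and -0.62 with the spike-in at 2 and 4 µM), with CD14, a receptor for bacterial lipids, 20.1-fold higher at 4 µM. Endothelial markers had 0.79, 1.30 and 1.00 (-0.82 at 4 µM), and 0.66, 0.32 and -0.07 without single spots of spot rows 1 to 200. Neuronal markers had -0.07, 0.85 and 1.02 (-0.80 at 4 µM), and -1.20, -0.71 and -0.70 without those spots. Photoreceptor markers had -0.38, 1.27 and 0.79 (-1.02 at 4 µM), and 0.78, 1.24 and -0.41 without those spots, with ROM1, a disc membrane protein, 15.6-fold higher at 1 µM. Mueller glia and astrocyte markers had 0.71, 0.73 and 0.82 (-0.04 and -0.99 at 2 and 4 µM), keratinocyte and epithelial markers 0.15, -0.67 and -0.20 (0.07, -1.45 and -2.02), with the epithelial cadherin CDH1 at least 4.76-fold higher at 1 µM, and melanocyte markers 0.47, 0.56 and 0.83 (-0.22 and -0.98 at 2 and 4 µM). Without those spots haematopoietic markers had 0.81 at 1 µM, Mueller glia and astrocyte markers 0.44 at 2 µM, keratinocyte and epithelial markers 0.49, -0.27 and -0.44, and melanocyte markers 1.27 and 2.14 at 1 and 2 µM. The measured members were few, from 5 endothelial to 15 haematopoietic genes at 4 µM. Without those spots 3, 3 and 2 endothelial genes were left at the 3 doses, 4, 4 and 3 neuronal and 4, 4 and 3 photoreceptor genes. At 1 and 2 µM 3 and 4 melanocyte genes were left, so changes of these medians are unsure.

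Histone genes gave values in both directions, such as H2BC21 at least 12.7-fold higher at 1 probe (log2 -0.17 at a second) and H1-1 22.9-fold lower at 1 µM, and as near-identical copies they are uncertain.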
